A study of Mus musculus with 11 samples.

How the data were processed

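Whole livers and liver tumours of male mice were collected for RNA sequencing, per the labels' protocols. The submitters' processing notes name STAR and Cufflinks and the builds mm9 and mm10, without versions or roles, and the series' design text says that gene lists came from Cufflinks with p and q thresholds of 0.05 and a fold change of 1.5 for overlaps. The values used here come from 1 deposited table comparing C with KO, in the layout of a Cuffdiff gene test. Per the file headers, the authors gave 1 FPKM value (fragments scaled to transcript length and to the fragments sequenced) for each side, with the replicates already combined. Per the file headers, the authors also deposited a log2 fold change of KO over C, a test statistic (a score without a fixed range), a p-value and a q-value. The file names no genome build. Its loci overlapped the gene of the same symbol in the GRCm38 annotation for 10461 of 10481 symbols (99.8%), so positions are given as GRCm38, which is mm10.

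The columns named C and KO were assigned to the 4-month control and knockout livers because the titles of these samples begin with C- and KO-. No other sample is titled KO; the 22-month controls, titled Control, also begin with C, and the C column was taken as the 4-month controls because they share the short title form and the age of the KO samples. The titles and the source names of the 3 KO samples disagree, and titles were used. The control mice are described without Cre, so an effect of Cre activity cannot be separated from an effect of Tdg. The comparison of 22-month control livers with tumours was not analysed here. Of the table's lines, 1 was emptied for this work. Without values per animal, no error between replicates, no test leaving out a liver, and no test of other groupings of the 6 livers was possible, and p-values and q-values are those of the authors. How library depth limited each gene is unknown, because FPKM alone does not give read counts.

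Of 24340 rows, 10910 had been tested by the authors and 13430 had not. Of the tested rows, 6 had no finite log2 fold change and were left out, which leaves 10904. The deposited q-value equals a Benjamini-Hochberg adjustment of the deposited p-value over tested rows within 5.5e-05. The log2 fold change differs from the ratio of the 2 FPKM values by over 0.001 in 1 tested row. The median log2 fold change of the 10420 tested genes with at least 1 FPKM on both sides was 0.01. Repeated symbols numbered 0, and 2349 tested rows share their listed locus with another row, so that reads of overlapping genes and of near-identical copies may be divided between rows in a way the table does not show.

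A gene was called at a q-value under 0.05. Before the data were examined, 45 gene lists, the tests and the rule for named genes were fixed. For each list, the share of called genes was set against all other tested genes with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. The deposited p-values of the members were also adjusted over the list alone, and the median log2 fold change was compared with 10000 random lists matched on mean FPKM in 20 bins as a description. The mitochondrially encoded genes had 0 tested members. Named genes are Tdg, the 10 largest rises and 10 largest falls among called genes with at least 1 FPKM on 1 side (leaving out predicted genes, clone names, small RNAs and joined symbols), up to 4 called members of each list by size of change, and 18 liver, cell cycle and DNA repair genes named whether called or not. Hspa5, Asns, Fga, Fgb, Fgg, Hp, Gm9855, Rps28, Cers6, Il1r1, Zbtb16, Slc39a14, Slc39a10, Syt1 and the Y-linked, nucleolar and placental genes fall outside this rule and were chosen after their values were seen. Cirbp, Rbm3 and Slc30a1 also fall outside it; they were chosen after the patterns they test had been seen and before their own values were. Genes within 10 Mb of Tdg were compared with all other tested genes by Fisher's exact test. The annotated transcripts of Gm9855 were aligned to those of Tdg with BLAST 2.17.0 at 90% identity or more.

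Alternatives were a q-value under 0.01, Bonferroni and Benjamini-Hochberg adjustment recomputed here, filters at 1 FPKM, 1 row per symbol, log2 values centred on the median, folds from FPKM + 1 and FPKM + 0.1, a fold of at least 2, windows of 5 Mb, 20 Mb and the chromosome, and limma's cameraPR on the ranks of the deposited test statistic with preset correlations of 0.01 and 0.05. Ranks were chosen after seeing the data because a few small RNA rows have extreme statistics. The steps were tested on simulated data with 10904 genes, 200 of them changed, with gene-level errors taken from the deposited p-values. Of the changed genes, 56.7% were called at a fold of 1.5, 91.0% at 2 and 97.0% at 4, with 7 calls among unchanged genes. The 1 planted list, a mix of raised and unchanged genes, had a Fisher's exact test adjusted p of 1.91e-05. Of 44 lists of unchanged genes, 0 passed that test, and 3 had a median outside the central 95% of random lists. Errors were drawn independently for each gene and few unchanged genes were called. The simulation therefore does not show how often lists pass falsely where many genes are called or genes move together. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.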

Results

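RNA was sequenced from whole livers and liver tumours of male C57BL6 mice. Experimental animals carried 1 floxed and 1 null allele of Tdg together with a ubiquitously expressed, tamoxifen-inducible Cre recombinase. Tdg encodes thymine DNA glycosylase, a base excision repair enzyme that also removes oxidised forms of 5-methylcytosine during active DNA demethylation. Controls had floxed Tdg alleles and, per the labels' protocols, both kinds of mice received tamoxifen. The labels describe 11 samples: 3 control livers and 3 livers titled KO taken 4 months after tamoxifen, 3 control livers at 22 months, and 2 hepatocellular carcinomas from mutant mice at 22 to 24 months. The 22-month livers and the tumours were not analysed here. The 3 livers titled KO have a source name that describes them as control livers, so they were grouped by title, and the direction of every comparison rests on the names C and KO.

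The authors' deposited table gives 1 pooled FPKM value per gene for each side, a log2 fold change, a p-value and a q-value, with no value per animal. The spread between the 3 livers of a group therefore could not be examined, and the depth of the libraries is unknown. Of 24340 rows, 10910 were tested by the authors, and 10904 of these have a finite log2 fold change. A gene is called here when its deposited q-value was under 0.05. Fold changes compare the side labelled KO with the control side.

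The targeted gene was examined first. In the authors' deposited table Tdg had 1.11 FPKM on the control side and 0.960 FPKM on the side labelled KO, a log2 fold change of -0.21 that did not pass the test (p = 0.515, q = 0.776). The listed locus of Tdg spans positions 82629838 to 82690650 of chromosome 10, counted from 1, and also takes in the neighbouring gene Glt8d2. The same table lists a row named Gm9855 at this same locus, with 0.416 FPKM on the control side and 1.21 FPKM on the side labelled KO (log2 fold change 1.54, q = 0.200). The GRCm38 annotation used here places Gm9855, a processed pseudogene, elsewhere on chromosome 10, at 42054113 to 42055306, so it is uncertain which transcripts the row measures. The annotated Gm9855 transcript matches a Tdg transcript at 99.2% identity over its whole length of 1194 bases, so the split of reads between the 2 rows is uncertain. A further annotated processed pseudogene, Tdg-ps, matches a Tdg transcript at 98.7% identity over 2968 bases and has no row of its own in the rows used here. A gene-level FPKM also does not show whether particular exons were lost. Because the table does not show a lower Tdg level, the sides are named throughout by their labels.

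The first comparison asked which genes differed between the 4-month livers labelled knockout and control, before tumours were sampled. The authors' deposited table called 1621 genes, 14.9% of those tested, of which 946 were higher and 675 were lower on the side labelled KO. With the fold change of at least 1.5 that the series applied to gene overlaps, 568 were higher and 406 lower. The median fold change was 1.56 among genes called higher and 1.56 among genes called lower. None of the called genes could pass a Bonferroni threshold, because the smallest deposited p-value, 5e-05, is too large for it over 10904 tested genes. That value is shared by 620 tested genes, so the outcome says nothing about the size of their changes.

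Among called genes with at least 1 FPKM on 1 side, leaving out predicted genes, clone names and small RNAs, the largest rise in the authors' deposited table was that of Mt2, a metallothionein (a small metal-binding protein), from 22.9 to 810 FPKM (log2 fold change 5.15). It was followed there by Cidec, a lipid droplet protein, from 0.717 to 14.1 FPKM (4.29), and the metallothionein Mt1, from 45.5 to 859 FPKM (4.24). Tnfrsf12a, the receptor of the cytokine TWEAK, rose by a log2 fold change of 3.15, and Cxcl1, a neutrophil-attracting chemokine, by 2.97 in that deposited table. The other large rises there were those of Ces2b (2.92), Ugt2b37 (2.92), Grhl1 (2.66), Ppl (2.53) and Fkbp5 (2.47), the last a glucocorticoid-induced co-chaperone. Each of these 10 genes had q = 0.00088, the smallest q-value in the deposited table. Ces2b and Ugt2b37 belong to multigene families whose members can share reads.

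Among the same called genes, the largest falls in the authors' deposited table were those of Rfx4 (log2 fold change -3.17), Clec2h (-2.64), the pro-apoptotic gene Bmf (-2.59), Ppp1r3g, a regulatory subunit that directs a phosphatase to glycogen (-2.45), and the imprinted noncoding RNA Meg3 (-2.44). They were followed in that deposited table by Trib3 (-2.12), a pseudokinase of the integrated stress response, Cxcl13 (-2.08), Fam65b (-1.97), the nuclear receptor Nr4a1 (-1.87) and Tff3 (-1.85). Tff3, a secreted peptide, went from 51.5 to 14.2 FPKM. Meg3 had q = 0.00347 and the other 9 had q = 0.00088 in the authors' deposited table.

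**Figure D1:**
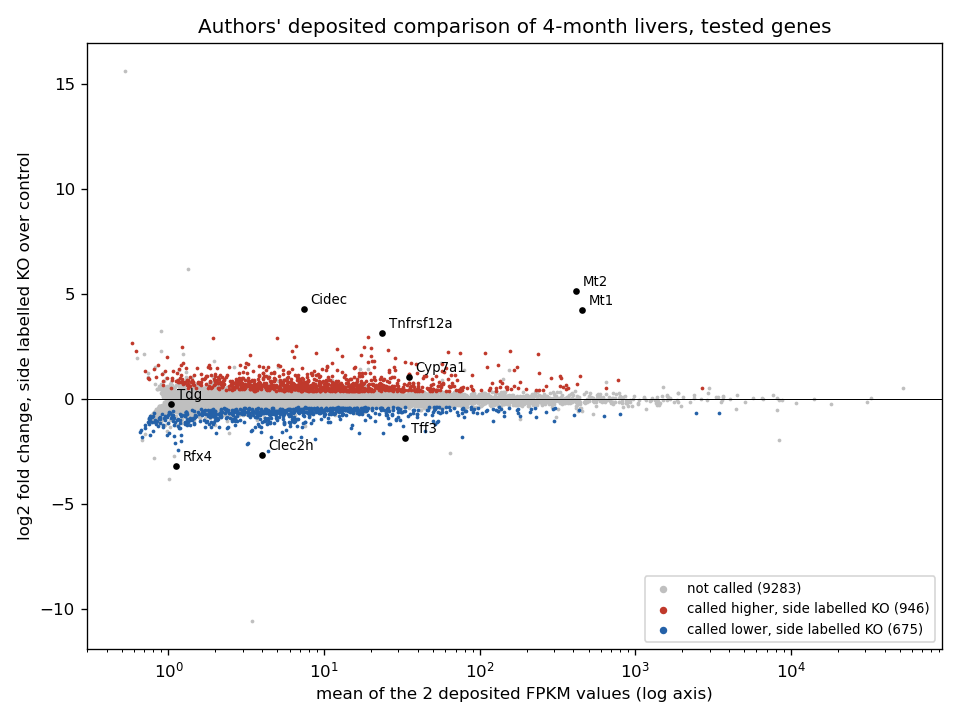
Log2 fold change of the side labelled KO over control against the mean of the 2 deposited FPKM values (log axis), 1 point per tested gene, with 946 called genes higher in red, 675 called genes lower in blue, genes not called in grey and the genes with a written name in black. Mt2 and Mt1 lie far above genes of similar level, at 5.15 and 4.24, and Tdg lies near 0 at -0.21; grey points far from 0 are genes that the authors tested and did not call.

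The second question was which groups of liver genes contained more or fewer called genes than the rest of the table. Of 45 gene lists, 44 had a tested member, and the share of called genes differed from that of all other tested genes for 12 of them (Fisher's exact test, two-sided, Benjamini-Hochberg over lists). In 10 lists the share was higher and in 2 it was lower. As a description, the median log2 fold change of 8 lists lay below and of 10 lists above the central range of 95% of random lists of equal size and expression. Genes are not independent replicates, so these tests describe the genes of the authors' deposited table. Unlike the random lists, Fisher's test was not matched on expression. Differences in level between a list and the other genes were therefore not accounted for in it. Set tests of direction with an estimated correlation could not be run without values per animal, and with preset correlations several of the 12 did not pass, as given beside each list.

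Most heat shock genes were called higher. Of 14 tested heat shock genes, 12 were called higher and none lower in the authors' deposited table (13 higher when adjusted over the list alone, Fisher's exact test adjusted p = 3.36e-07). Hsph1, an exchange factor of the HSP70 chaperones, had a log2 fold change of 1.95, the small chaperone Hspb1 1.77, Hsp90aa1 1.50 and Hspa1b 1.26 in the authors' deposited table. Hspa1b has a near-identical neighbouring copy, Hspa1a, and its value is uncertain for that reason. The unfolded protein and integrated stress response list had 12 members called higher and 2 lower among 31 tested in the authors' deposited table (15 and 3 when adjusted over the list alone, adjusted p = 0.00117; 0.0907 with a preset correlation of 0.05). The called members higher by the most there were Creld2 (1.75), the transcription factor Xbp1 (1.39) and Manf (1.12), and Hspa5, the main chaperone of the endoplasmic reticulum, rose from 284 to 604 FPKM. The 2 members called lower in the authors' deposited table were Trib3 (-2.12) and asparagine synthetase, Asns (-1.09), both targets of the transcription factor ATF4. The cold-induced genes Cirbp and Rbm3 had log2 fold changes of -1.29 (q = 0.739) and -0.23 (q = 0.492) in the authors' deposited table and were not called; the listed locus of Cirbp takes in other genes, which makes its value uncertain.

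The acute phase list contained more called genes than other genes, all of them higher, while most of its members were not called. The authors' deposited table called 12 of 30 tested members higher and none lower (12 also when adjusted over the list alone, Fisher's exact test adjusted p = 0.00522), and 18 were not called. Besides Mt1 and Mt2, they included the metalloreductase Steap4 (log2 fold change 2.29) and the serum amyloid gene Saa2 (2.21), which shares long stretches with Saa1. The abundant fibrinogen chain Fgb had 2632 and 3239 FPKM and was not called (q = 0.343) in the authors' deposited table, nor were Fga (q = 0.43), Fgg (q = 0.542) and haptoglobin, Hp (q = 0.261). Of 19 inflammatory cytokine and chemokine genes tested there, 5 were called higher, among them Cxcl1 and Tlr2 (0.89), and 2 lower, Cxcl13 and Tnfaip3 (-0.77), a share that did not pass the test (adjusted p = 0.0524). The median log2 fold change of these 19 genes was -0.22, with 8 above 0 and 11 below, so the list as a whole did not lean higher. Beside these groups, 24 tested macrophage markers had a median log2 fold change of -0.20, with 1 called higher (Cd163, 0.45) and 3 lower (Marco, -1.09; Lyz2, -0.61; Adgre1, -0.53) in the authors' deposited table (adjusted p = 0.895; 0.00968 and 0.118 for a shift with preset correlations of 0.01 and 0.05).

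Genes of glucose and lipid handling changed in both directions. Among 21 tested glycolysis genes, the authors' deposited table called 7 higher and 2 lower (8 and 2 when adjusted over the list alone, adjusted p = 0.00915; 0.138 to 0.395 with preset correlations). Glucokinase, Gck, which traps glucose in hepatocytes, rose by a log2 fold change of 1.29, Pfkfb3 by 0.91, Gpi1 by 0.73 and Pfkfb1 by 0.66 there. Of 22 fatty acid synthesis genes tested in the authors' deposited table, 8 were called higher and 2 lower (also 8 and 2 when adjusted over the list alone, adjusted p = 0.00522; 0.45 to 0.692 with preset correlations). Lpin1 rose by 1.54, Thrsp by 0.90, Elovl6 by 0.65 and Fasn, the fatty acid synthase, by 0.46 (q = 0.0443), whereas Insig2 had -0.77, all in the authors' deposited table. Srebf1, a transcription factor of this pathway, had -0.31 and was not called (q = 0.168) in the deposited table. For both lists the share of calls with a fold of at least 1.5 did not differ from other genes (adjusted p = 0.108 for glycolysis and 0.121 for fatty acid synthesis).

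The insulin and IGF signalling list had 3 members called higher and 7 lower among 22 tested in the authors' deposited table (3 and 9 when adjusted over the list alone, adjusted p = 0.00522; 0.2 to 0.475 with preset correlations, 0.0524 with calls of at least 1.5-fold). Socs2 (log2 fold change 2.06) and Socs3 (1.41), which encode inhibitors of cytokine signalling, were called higher in the authors' deposited table, and the insulin receptor substrate Irs1 (-0.93) was called lower. For gluconeogenesis and glycogen, 2 of 20 members were called higher and 5 lower in the authors' deposited table, which did not pass the test of share (adjusted p = 0.0655). Its called members included the glycogen-targeting subunits Ppp1r3g (-2.45) and Ppp1r3b (1.15), the coactivator Ppargc1a (-0.91) and tyrosine aminotransferase, Tat (-0.72). The gluconeogenic enzymes G6pc (0.34, q = 0.129) and Pck1 (-0.33, q = 0.201) were not called in the authors' deposited table. Of 38 genes of fatty acid oxidation and PPARA targets, 8 were called higher and none lower in that deposited table, including Cyp4a14 (1.81), Acot3 (1.69) and Cyp4a10 (1.01), with no difference in share (adjusted p = 0.473). Of 25 cholesterol synthesis and uptake genes, 1 was called higher and 7 lower in the authors' deposited table (adjusted p = 0.0707). Hmgcs1 (-0.81), Insig1 (-0.80) and Mvk (-0.57) were among the 7, and Hmgcr, the rate-limiting enzyme of cholesterol synthesis, was the 1 called higher (0.58).

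Bile acid genes differed one by one. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, went from 22.8 to 47.0 FPKM in the authors' deposited table (log2 fold change 1.04, q = 0.00088). Cyp8b1, which sets the proportion of cholic acid, went from 172 to 113 FPKM (-0.60, q = 0.00088) and Hsd3b7 had -0.63 in that deposited table, and the other 13 of 16 tested synthesis genes were not called (adjusted p = 0.893). Among 12 transport genes the bile acid importer Slc10a2 rose from 6.26 to 33.8 FPKM (2.43), while Abcg8 (-0.52) and Abcc2 (-0.49) were called lower in the authors' deposited table (adjusted p = 0.593). The hepatocyte transporters Slc10a1 (-0.17, q = 0.549) and Abcb11 (-0.29, q = 0.217) were not called there. The bile acid receptor gene Nr1h4 (0.05, q = 0.888) was not called in the authors' deposited table, whereas its target Nr0b2 rose by 0.72 (q = 0.00088). In the receptor axis list of 16 tested genes, 3 were called higher and 2 lower in the authors' deposited table (adjusted p = 0.187), with Hnf4a at 0.81, Sdc4 at 0.62 and Klb at -0.57.

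Sex-biased liver genes contained more calls than other genes. Among 26 tested male-biased genes, the authors' deposited table called 1 higher (C4a, log2 fold change 2.09) and 9 lower (2 and 14 when adjusted over the list alone, Fisher's exact test adjusted p = 0.0122). Elovl3 (-1.10), Moxd1 (-0.95) and the major urinary protein gene Mup21 (-0.79) fell the most in the authors' deposited table. The Mup genes are near-identical copies and uncertain, and without them, an alternative chosen after seeing the data, 1 was higher and 5 lower among 19 genes (adjusted p = 0.136). The share called was then 31.6% against 38.5% with them, and the median log2 fold change -0.29 against -0.39, so the call ended with fewer genes and a somewhat smaller share. Of 10 tested female-biased genes, 3 were called higher and 2 lower in the authors' deposited table (the same counts when adjusted over the list alone, adjusted p = 0.0379; 0.979 to 0.987 with preset correlations), and their median (-0.24) and mean (0.03) log2 fold change differed in sign. Cyp2c69 (-1.72) was called lower, and Acot3 (1.69), Fmo2 (1.02) and Cyp4a10 (1.01) higher, in the authors' deposited table. Acot3 and Cyp4a10 are also on the list of PPARA targets, so these 2 lists are not separate evidence. The Y-linked genes Ddx3y (0.16, q = 0.51) and Uty (-0.10, q = 0.77) were expressed on both sides and not called there.

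Signalling genes of the TGF-beta and BMP pathways had 8 members called higher and 2 lower among 23 tested in the authors' deposited table (also 8 and 2 when adjusted over the list alone, adjusted p = 0.00576; 0.223 to 0.475 with preset correlations). Id1 (log2 fold change 1.40), Inhbb (1.36) and Id3 (1.14) rose and Fst, an activin-binding protein, fell (-1.01) in the authors' deposited table. Of 21 immediate early genes, 6 were called higher and 3 lower there (7 and 4 when adjusted over the list alone, adjusted p = 0.00915; 0.645 to 0.826 with preset correlations), with Jun at 1.01 and Maff at 0.79, and with Nr4a1 (-1.87) and Nr4a2 (-1.19) lower in the authors' deposited table.

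A pair of groups contained fewer calls than other genes. None of 52 tested cytosolic ribosomal protein genes (adjusted p = 0.00522; 0.124 to 0.475 with preset correlations) and none of 33 oxidative phosphorylation subunits (adjusted p = 0.0409; 0.982 to 0.987) was called in the authors' deposited table, nor when adjusted over the list alone. With calls of at least 1.5-fold, which are fewer among other genes, the shares no longer differed (adjusted p = 0.0574 and 0.28). The ribosomal and oxidative phosphorylation genes had no call to lose, so that outcome does not bear on them. Rps28, which was not on the list and was noticed after its value was seen, was called lower (log2 fold change -1.79) in the authors' deposited table.

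**Figure D2:**
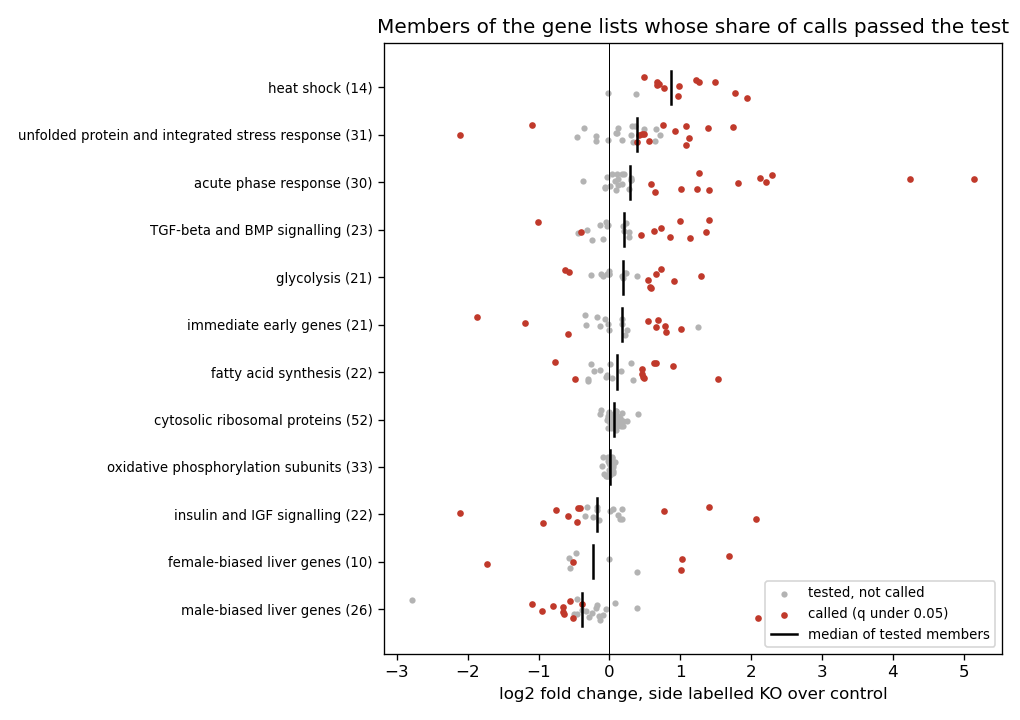
Log2 fold change of the side labelled KO over control for each tested member of the 12 gene lists whose share of called genes passed Fisher's exact test, 1 point per gene, red where called and grey where not, with a black bar at the median; the number of tested members follows each name. The heat shock genes have the highest median, 0.87, the male-biased genes the lowest, -0.39, and the ribosomal and oxidative phosphorylation genes contain no called member.

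Repair, demethylation and proliferation genes did not stand apart as groups. Of 19 tested base excision repair genes, Ung (log2 fold change 1.51) and Apex2 (0.69) were called higher and none lower in the authors' deposited table, and of 16 DNA methylation and demethylation genes, Gadd45a (0.81), Mbd1 (0.68) and Apobec1 (0.44, q = 0.0466) were called higher (adjusted p = 1 and 0.893). Tet2 (-0.06, q = 0.881) and Tet3 (-0.28, q = 0.191) were not called in that deposited table, and Tet1 and Mbd4 were not tested by the authors. The cyclin-dependent kinase inhibitor Cdkn1a rose from 1.24 to 3.64 FPKM (1.55) in the authors' deposited table, where 3 of 25 p53 targets were called higher and 3 lower (adjusted p = 0.473). Of 19 cell cycle genes tested there, 3 were called higher, Rrm2 (1.47), Ccne1 (1.14) and E2f8 (0.83), and Cdk2 was called lower (-0.57) (adjusted p = 0.727). The proliferation marker Mki67 was not tested by the authors, at 0.349 and 0.389 FPKM. The fetal liver gene Afp had -0.67 and was not called (q = 0.188) in the authors' deposited table.

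Of 10 tested fetal liver and tumour-associated genes, the authors' deposited table called 4 lower and none higher (1 higher and 4 lower when adjusted over the list alone, adjusted p = 0.133), namely Meg3, Tff3, H19 (log2 fold change -1.04) and Rbp1 (-0.62). With calls of at least 1.5-fold the share passed the test (adjusted p = 0.0471). Of 20 tested genes restricted to placenta, 12 were called lower and 8 were not called in the authors' deposited table, with a median log2 fold change of -0.96 over the 20, and Meg3 and H19 are also expressed in placenta. Without the list's placenta-expressed members, an alternative chosen after seeing the data, 2 of 6 were called lower (adjusted p = 0.441).

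The shares of calls in the remaining lists did not pass the test in the authors' deposited table. Retinoid genes had 1 member called higher and 5 lower among 21, including the retinoic acid hydroxylase Cyp26a1 (log2 fold change -1.54) and the receptor Rarb (-0.92) (adjusted p = 0.253). Clock genes had 2 higher and 3 lower among 18 in the authors' deposited table, with Nfil3 at 0.82, Nr1d1 at -0.69 and Dbp at -0.57 (adjusted p = 0.351). Of 29 hepatocyte markers, 4 were higher and 1 lower, with the transcription factors Foxa3 (1.35), Hnf4a (0.81) and Onecut1 (0.77) rising in the authors' deposited table (adjusted p = 0.812). The remaining cell type lists gave 3 higher and 4 lower of 28 for stellate cells and fibrosis (adjusted p = 0.351), 2 higher and 1 lower of 23 for sinusoidal endothelium (1), 1 higher and 1 lower of 7 for cholangiocytes (0.492), 1 higher and none lower of 3 for neutrophils (0.581), and none higher and 1 lower of 3 for B and plasma cells (0.581), in the authors' deposited table. No T and NK cell marker was called with 1 tested (adjusted p = 1), no blood marker of 6 (0.812), and no adipocyte, muscle or pancreas marker of 4 (1). Zonation genes gave 1 higher and 1 lower of 20 for pericentral (adjusted p = 0.895) and 2 and 2 of 18 for periportal hepatocytes (0.557). Xenobiotic metabolism had 4 higher and 1 lower of 37 (adjusted p = 1), NRF2 targets 3 higher and none lower of 17 (0.893), interferon response 5 and 3 of 39 (0.581), antigen presentation none and 2 of 17 (1), complement and coagulation none and 1 of 35 (0.136), and Wnt and Hippo targets 1 and 3 of 13 (0.253).

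Genes near the targeted locus were compared with the rest, because knockout and control alleles can carry different flanking DNA. Within 10 Mb of Tdg, 22 of 173 tested genes (12.7%) were called in the authors' deposited table, 15 higher and 7 lower, against 14.9% of all other tested genes (Fisher's exact test, two-sided, p = 0.517). The share of calls near Tdg did not differ from the rest. Rfx4, the largest of the falls named above (log2 fold change -3.17), lies within this window, at 84756048 to 84906538. A share of calls does not test single genes, so an effect of flanking DNA on Rfx4 or another gene of the window stays open.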

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

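The tests of exchanged columns, of feeding state and of placental transcripts were chosen after the results they bear on had been seen; the alignment of Gm9855 was chosen after its FPKM values but before its sequence had been examined, and Cirbp and Rbm3 after the chaperone pattern but before their own values. Rows that the authors had not tested contain signal on 1 side only: 12 rows, all of them small RNA symbols, are listed at 0 for control and at 1 FPKM or more (up to 2586 FPKM) for the side labelled KO. The reverse was found for 8 small RNA rows, at up to 2528 FPKM. No fold is given for rows listed at 0.

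Tdg was not called lower on the side labelled KO. The annotated Gm9855 transcript aligned to a Tdg transcript over 100% of its length, which is consistent with reads being shared between the 2 rows, both of which the table puts at the Tdg locus. Tdg-ps, a longer copy without a row of its own in the rows used here, could take or give reads too, so the rows do not show the total of Tdg-like reads. An exchange of the 2 columns cannot be told apart from the labelled direction by Tdg, whose log2 fold change of -0.21 passed no threshold either way. A deletion that leaves most of the transcript in place stays open, since the table has no value per exon, as does incomplete recombination. The loss of Tdg named by the design was therefore not shown by this table.

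On the side labelled KO 12 of 14 heat shock genes were called higher, and of 31 unfolded protein and integrated stress response genes, which include the endoplasmic reticulum chaperones, 12 were called higher and 2 lower (adjusted p = 0.0907 with a preset correlation of 0.05). A difference in body temperature or time of day at collection stays open, because the higher of the log2 fold changes of the cold-induced genes Cirbp and Rbm3 was -0.23 and neither was called. Clock genes also bear on time of day, and 2 of 18 tested were called higher and 3 lower (Fisher's exact test adjusted p = 0.351). Among them Nfil3 had 0.82, Nr1d1 -0.69 and Dbp -0.57. No test of time of day had been set on the clock genes, so they do not decide it. A difference in feeding state also stays open: of 34 called fasting- and feeding-induced genes, 22 (64.7%, exact 95% interval 46.5 to 80.2%, taking genes as independent) moved as in feeding. This split lay within the range set as even, which was to count against feeding. The interval, added to that rule later, reaches beyond that range, so the question was left open. The 16 called fasting-induced genes split evenly, 8 higher and 8 lower, and the feeding-induced genes had 14 higher and 4 lower. Loss of Tdg, the difference the design names, remains among the open explanations, as does Cre activity.

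The authors' deposited table assigns reads of these male livers to placental genes, of which 12 of 20 tested were called lower on the side labelled KO and 8 were not called. Prl3b1, a placental lactogen, had 11.3 and 5.16 FPKM, Tpbpb, a trophoblast gene, 11.4 and 5.64, and Ceacam11 7.63 and 3.43 in the authors' deposited table. Of 57 placenta-restricted genes, 29 (50.9%) had at least 0.5 FPKM on the control side, just past the 50% or more that RNA or reads from a placenta sample were taken to need. Of the 47 that had not been noticed before the list was written, 19 (40.4%) had that level, so the test leaves this explanation open. The 29 genes had a spread between their log2 fold changes of 0.42 (SD). On the control side, 35 genes restricted to other organs had a median of 0 FPKM, and 3 of them had at least 0.5 FPKM. The 1 of them that was tested, Syt1, had 5.50 FPKM and was also called lower (log2 fold change -0.69). Misassigned reads of liver-expressed paralogs stay open, since placental genes of families without such a paralog had a median of 0.273 FPKM on the control side, between the bounds set for that test, although Tpbpb and Prl3b1 belong to those families. Of the 31 genes of those families, 13 had at least 0.5 FPKM on the control side. The 9 tested all had a log2 fold change below 0, and 4 were called lower. As the list was drawn, paralog reads would not account for these genes. No biological explanation was tested.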

How the results depend on the processing

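The alternative lists without Mup genes and without placenta-expressed genes, the counts without placenta-restricted genes, and the use of ranks were chosen after seeing the data. No paired analysis was possible because the table has 1 pooled value per side, and for the same reason no liver could be left out. At a q-value under 0.01 the calls numbered 612 higher and 387 lower. Bonferroni adjustment left 0 in each direction, with or without the fold threshold, because the smallest deposited p-value, shared by 620 genes, is too large for it; 2807 tested genes had an unadjusted p under 0.05. A fold of at least 2 left 177 higher and 125 lower, and folds from FPKM + 1 left 227 lower at 1.5-fold. Across the other alternatives the counts stayed within 1.5 times the reported ones, including 663 lower (394 at 1.5-fold) without placenta-restricted genes. Under cameraPR 7 lists passed with a preset correlation of 0.01 and 3 with 0.05, of which 4 and 3 were among the 12 reported. The 3 were heat shock, acute phase response and male-biased genes. With 0.01 cameraPR also called PPARA targets higher (adjusted p = 0.00968), and cholesterol synthesis (0.0189) and macrophage markers (0.00968) lower. cameraPR tests a shift in 1 direction, whereas Fisher's test counts calls in either. With calls of at least 1.5-fold 8 lists passed, 7 of them among the 12. The log2 fold change of Tdg was -0.22 centred and -0.11 from FPKM + 1, settings that leave its q-value as deposited, and the recomputed adjusted p was 0.776. The share of calls near Tdg ranged from 12.1 to 15.6% with no test passed. With filters at 1 FPKM on 1 side or on both, the 144 and 127 named genes left kept their side of the threshold. Centring and FPKM + 1 alter only the log2 fold change, so they could not change these calls. Stricter thresholds do change them. A q-value under 0.01 ends calls such as those of Fasn (q = 0.0443) and Apobec1 (q = 0.0466), and Bonferroni adjustment ends all. What depth limits is unknown, as the table gives no counts.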

Other observations

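The lists in these paragraphs and the tests on them were chosen after the values were seen, except the test of Slc30a1 and the list of macrophage markers. Of 94 tested genes of ribosome production in the nucleolus, 59 were called higher, 0 lower and 35 not called in the authors' deposited table, with a median log2 fold change of 0.62. The list was drawn up after its theme had been noticed in the same values, so no test is given and the counts only describe this table. Examples in that deposited table are Rrp12 (1.62), the methyltransferase Nop2 (1.57), the box C/D particle proteins Nop58 (1.54) and Nop56 (1.16, q = 0.0432), Tsr1 (1.54), and the RNA polymerase I subunits Polr1e (1.48), Polr1a (1.14) and Polr1b (0.86). Cytosolic ribosomal protein genes, by comparison, had 0 calls among 52. Of these, 43 had a log2 fold change above 0 and 9 below, with a small median of 0.07.

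Other genes with large rises in the authors' deposited table, chosen after their values were seen, were Cers6 (log2 fold change 2.40), the interleukin 1 receptor Il1r1 (2.33) and the transcription factor Zbtb16 (2.18). The zinc importers Slc39a14 (1.13) and Slc39a10 (1.05), chosen in the same way, were called higher there.

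For the rise of metallothionein and acute phase genes, 3 tests were looked at before those of the placental transcripts were written, and they are given for completeness. The zinc exporter Slc30a1 had a log2 fold change of 0.12 (q = 0.656) in the authors' deposited table, which does not decide on a metal load. Of 13 called glucocorticoid-induced genes other than Mt1, Mt2 and Lcn2, 61.5% were higher (8 of 13, exact 95% interval 31.6 to 86.1%). This split lay within the range set as even, which was to count against glucocorticoids. The interval, added to that rule later, reaches beyond that range, so the glucocorticoid level was left open. Of 24 tested macrophage markers, 79.2% were below 0 (exact 95% interval 57.9 to 92.9%), and 3 were called lower against 1 higher. Both intervals take genes as independent, and the fall itself had an adjusted p of 0.118 with a preset correlation of 0.05, so these values argue against more macrophages on the side labelled KO and do not show fewer.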
